A study of Mus musculus with 12 samples.

How the data were processed

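RNA was extracted from aortic tissue between the left subclavian artery and the diaphragm of 12 Eln+/- mice, 4 per group, and libraries followed standard Illumina procedures, per the labels' protocols. Tissue was kept frozen in a preservative until all samples could be extracted together, per the labels' protocols. Extraction therefore had no batches in the labels, but the day and hour of collection, the cage and the sex are not given there. All 12 libraries held reads of Y-linked genes (Ddx3y between 98.8 and 161 CPM), and Xist had 9 to 46 reads per library.

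The deposited count files hold whole-number read counts per gene, made with featureCounts 1.4.6-p3 on GENCODE mouse release M13, per the file headers. The alignment index named there was built with STAR 2.5.3a, and the genome build is GRCm38 per the submitters' processing notes. The recorded counting options assigned reads that map to several places, and reads over several genes, to each of them, ignored duplicates and set no strand. Near-identical copies (Hspa1a and Hspa1b, the haemoglobin genes), overlapping genes and antisense partners therefore share reads, and their values are uncertain. The same holds for the short genes Mir143 and Mir145a, which lie inside a longer transcript. The deposited series tables give log2 values, which equalled log2(count / size factor + 1) in every library, with size factors identical to those that DESeq2 computes from the deposited counts. DESeq2 is among the tools in the submitters' processing notes. These tables were used for gene symbols and GRCm38 coordinates, and the counts were used for every test. Because the tables hold the same counts, the planned repeat on their counts was not run.

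Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 24660 of 50600 genes. TMM factors scaled the libraries, and CPM values quoted are edgeR's cpm, the counts divided by the TMM-scaled library size. One quasi-likelihood model (glmQLFit, robust) with 3 groups was fitted to all 12 libraries, and 3 contrasts were tested two-sided: on drug against control, off drug against control and off drug against on drug. P-values were adjusted by Benjamini-Hochberg over all genes, and an adjusted p below 0.05 made a call. Standard errors of log2 fold changes were derived from the F statistic. Errors beside CPM are SDs over 4 libraries, and errors beside log2 fold changes are SEs. Totals ran from 41524501 to 109423243 counts, so counting error was small beside the spread between mice for all but the lowest genes.

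Gene lists were written from textbook knowledge before the data were examined, as were the groups, the tests, the other settings and the rule for naming genes. There were 46 lists, covering matrix (8 lists, 203 genes tested), smooth muscle and channels, other cell types of the aorta, tissues beside it and general processes. Each list was tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 of the 46 lists passed in any comparison, and fry passed 10, 12 and 18 lists against 22, 15 and 22 with the preset value, in the order of the comparisons above. For on drug against control, 24 lists did not pass.

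Named genes were 10 fixed genes, the 6 largest rises and 6 largest falls per comparison among called genes with a mean log2 CPM of at least 1 and no overlap between groups (unnamed gene models and immune receptor segments left out), and up to 3 called members, by smallest adjusted p, of each list that passed and of each matrix list. Genes outside this rule are marked as chosen after their values were seen. Values of 4 named genes are not reported here, although the counts include them.

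Other settings fixed in advance were DESeq2 size factors in edgeR, library size without composition factors, no filter, a stricter filter (CPM of at least 1 in 4 libraries), DESeq2 1.42.0, limma-voom with quality weights, the 2 compared groups alone, a non-robust fit, replicate number as a block, each library left out in turn, scores of fat, skeletal muscle or immune genes as covariates, 1 surrogate variable from sva 3.50.0, a fold minimum and, for lists, removal of members held by other lists. For the overlap and fate counts they were DESeq2 calls, an adjusted p of 0.10, each library left out and the controls split 2 and 2. A covariate for Xist was planned only for groups that mixed libraries with and without it, and was not run. Chosen after seeing the data were a covariate from 10 clock genes, removal of the trend on transcript length and GC content, and leaving out 2 libraries together. Length and GC came from a GRCm38 transcript set and were known for 99.6% of tested genes.

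The steps were tested on simulated counts with the real means and library sizes, in which 200 of 24660 genes were changed. For on drug against control, 30% of genes changed 1.3-fold, 68% changed 1.5-fold, 96% changed 2-fold and 100% changed 4-fold were called. For off drug against control these shares were 36%, 70%, 96% and 98%, and for off against on drug 28%, 80%, 90% and 98%. False calls made up 5.16%, 5.06% and 6.92% of all calls. In these simulations, changes of about 1.3-fold were therefore mostly missed. The changed genes were drawn from those with a mean log2 CPM of at least 1. The 200 changed genes were far fewer than the 1743 to 3047 called in the data, which makes the Benjamini-Hochberg threshold stricter. The shares recovered thus do not carry over to the data, where on-drug calls had a median absolute log2 fold change of 0.39.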

Results

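Gene expression was measured by RNA sequencing in the descending thoracic aorta of C57BL/6J mice that carried 1 functional copy of the elastin gene (Eln+/-). Elastin is the protein of the stretchable lamellae of the arterial wall. Minoxidil, a vasodilator that opens ATP-sensitive potassium channels, was given in the drinking water. Of the 3 groups of 4 mice, control mice drank plain water. On-drug mice received minoxidil for 2 weeks from 2.5 months of age, and off-drug mice received the same course followed by 1 week of plain water. By this schedule the off-drug mice were about 1 week older at harvest, although every sample carried the labelled age of 3 months. Each of the 12 libraries came from a separate sample of its group.

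Count totals were high throughout. The libraries held between 41524501 counts (on-drug replicate 3) and 109423243 counts (on-drug replicate 1). Reads assigned to several genes entered these totals repeatedly, so the totals overstate the number of reads. The mitochondrial ribosomal RNA gene mt-Rnr2 took 8.73% of the counts on average. Of 50600 annotated genes, 24660 passed the expression filter. Spearman correlations of the counts between libraries of a group lay between 0.984 and 0.989, and every pair of libraries within a group differed by far more than sampling noise. In a principal component analysis the first component held 18.3% of the variance and the second 13.1%. On the first component the off-drug libraries lay apart from the other 8, and on the second the controls lay apart from the on-drug libraries.

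Because all mice were Eln+/-, the elastin transcript was examined first in every library. Eln (ENSMUSG00000029675.12, chromosome 5, 134702593 to 134747323, minus strand, GRCm38) was measured at 480.2 ± 109 CPM (read counts scaled to library size; mean ± SD, n = 4) in controls, 839 ± 227 CPM on drug and 234 ± 25.8 CPM off drug. Individual controls ranged from 369.6 to 621 CPM. On-drug values ranged from 601 to 1090.2 CPM and off-drug values from 209 to 268 CPM. The on-drug increase over controls, a log2 fold change of 0.80 ± 0.21 (SE), narrowly missed the threshold with an adjusted p of 0.0523 in edgeR's quasi-likelihood test. It passed in 6 of 27 other settings, with adjusted p between 0.0042 and 0.154, among them without control replicate 1 (0.0267) and without on-drug replicate 1 (0.0193). After the drug-free week Eln stood below controls, at -1.03 ± 0.21 with an adjusted p of 0.0122. It also stood below the on-drug level, at -1.84 ± 0.22 with an adjusted p of 0.000431.

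**Figure D1:**
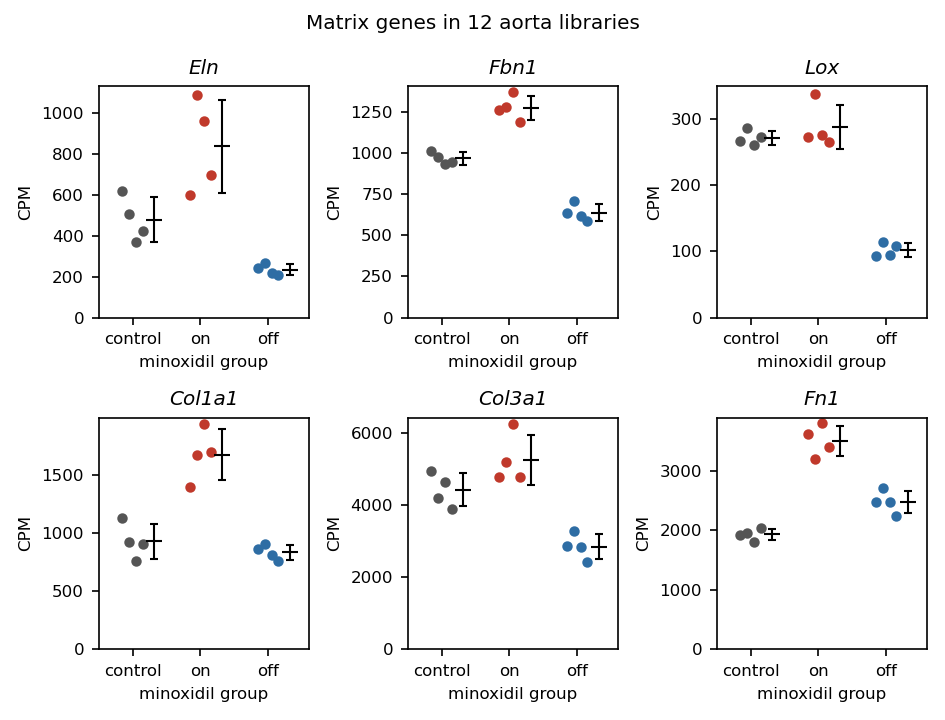
CPM (counts scaled to library size) of 6 matrix genes in each of the 12 aorta libraries (dots, linear axis from 0), with the mean and SD of each group of 4 beside them. Fbn1, Col1a1 and Fn1 were higher on drug than in controls, whereas Lox differed from controls in the off-drug group, where it averaged 102 CPM against 271 CPM.

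The first comparison asked how 2 weeks of minoxidil changed the aortic transcriptome. Structural genes of the extracellular matrix were higher on drug. Fibronectin (Fn1), a cell-adhesive glycoprotein, rose from 1935 ± 98.5 to 3512 ± 258 CPM (log2 fold change 0.86 ± 0.07, adjusted p = 2.9e-06). The alpha chain of type I collagen encoded by Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) rose from 929.5 ± 149.8 to 1674 ± 220.5 CPM (0.85 ± 0.11, adjusted p = 0.000668). Heat-shock chaperones moved the other way, with Hspa1a at 1898 ± 1032 CPM in controls and 379.7 ± 106 CPM on drug. Control replicate 3 stood above the other controls for this gene, at 3413 CPM against 1232 to 1690 CPM, and without it the log2 fold change was -1.88 (adjusted p = 0.0103) in place of -2.32. In total 1018 genes were higher and 725 lower on drug at an adjusted p below 0.05. Of these, 64 rose and 75 fell at least 2-fold.

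Of 23 elastic fibre genes 12 were called up and 0 down on drug, and 3 had a negative log2 fold change. There were 14 up when adjusted over the list alone. The list passed camera with an adjusted p of 1.6e-07, and had an adjusted p = 0.263 with an estimated correlation. Fibrillin-1 (Fbn1, ENSMUSG00000027204.13, chromosome 2, 125300594 to 125507993), the main microfibril protein, rose from 965 ± 36.9 to 1271 ± 74.4 CPM. Fibulin-2 (Fbln2) increased by 0.68 ± 0.08 and the cross-linking enzyme Loxl2 by 0.63 ± 0.10 on the log2 scale. Lox, the lysyl oxidase that cross-links elastin and collagen (ENSMUSG00000024529.13, chromosome 18, 52516069 to 52529867), had 271 ± 10.8 CPM in controls and 287 ± 33.5 CPM on drug, a difference within the replicate spread (adjusted p = 0.598).

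Interstitial collagens were called up in 11 of 18 cases and down in 0, or 14 up and 1 down adjusted over the list alone. Their median log2 fold change was 0.41, with a camera adjusted p of 2.4e-07 and an adjusted p = 0.263 with an estimated correlation. Col12a1 rose by 0.90 ± 0.10 and Col6a3 by 0.60 ± 0.07. Col3a1 (ENSMUSG00000026043.18, chromosome 1, 45311538 to 45349706), the most abundant of the named collagens, had a log2 fold change of 0.24 ± 0.10 that did not pass (adjusted p = 0.170). Among basement membrane genes 10 of 19 were up and 0 down (13 up adjusted over the list alone), including perlecan (Hspg2, 0.60 ± 0.09), nidogen-1 (Nid1, 0.49 ± 0.06) and Col4a2 (0.50 ± 0.08). Camera gave this list an adjusted p of 7.3e-08, and an adjusted p = 0.263 was obtained with an estimated correlation.

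Several lists of genes that modify or surround the fibrils were higher as well. Collagen-processing genes were up in 12 of 24 cases and down in 0, or 13 up and 2 down adjusted over the list alone (camera adjusted p = 1.1e-05, adjusted p = 0.592 with an estimated correlation). They included the procollagen C-proteinase Bmp1 (0.33 ± 0.06) and the collagen chaperone Sparc (0.58 ± 0.10). Matricellular glycoproteins were up in 12 of 34 cases and down in 0, or 15 up and 1 down adjusted over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.263 with an estimated correlation), with tenascin-X (Tnxb) up by 0.66 ± 0.06. Integrin and focal adhesion genes were up in 8 of 26 cases and down in 1, or 14 up and 1 down adjusted over the list alone. Their camera adjusted p was 1.4e-06 (adjusted p = 0.324 with an estimated correlation). The fibronectin receptor subunit Itga5 rose by 0.86 ± 0.10, while Itgb8, a subunit that activates latent TGF-beta, fell by 1.04 (SE 0.12). Proteoglycans (5 up and 2 down of 23) and matrix proteases with their inhibitors (5 up and 1 down of 36) did not pass, with camera adjusted p of 0.360 and 0.180.

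Vessel-lining and mast cell markers were also higher on drug. All 7 lymphatic endothelial markers had a positive log2 fold change, and 4 were called up, or 7 adjusted over the list alone (camera adjusted p = 1.7e-06, adjusted p = 0.263 with an estimated correlation). Prox1, the lymphatic identity factor, rose from 0.406 ± 0.0642 to 1.03 ± 0.211 CPM and the receptor Flt4 from 4.83 ± 1.16 to 9.17 ± 2.12 CPM. Endothelial genes were up in 5 of 22 cases and down in 0, or 8 up adjusted over the list alone (camera adjusted p = 0.00015, adjusted p = 0.594 with an estimated correlation). Among them von Willebrand factor (Vwf) increased by 0.58 ± 0.07. Mast cell markers were up in 3 of 9 cases, or 5 adjusted over the list alone, and camera gave 0.0036 (adjusted p = 0.594 with an estimated correlation). The 3 calls depended on single libraries. Cpa3 lost its call without control replicates 2 (0.0945), 3 (0.0628) or 4 (0.0951) or on-drug replicates 1 (0.0554), 3 (0.106) or 4 (0.0856), Mcpt4 without control replicates 2 (0.0905), 3 (0.0897) or 4 (0.0900) or on-drug replicates 3 (0.102) or 4 (0.10), and Mrgprb1 without control replicates 1 (0.0724), 2 (0.101) or 3 (0.127) or off-drug replicate 3 (0.0568) or on-drug replicates 1 (0.0688), 2 (0.0942), 3 (0.116) or 4 (0.0597). Contractile smooth muscle genes were up in 6 of 26 cases and down in 1, or 8 up and 1 down adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.0182, adjusted p = 0.594 with an estimated correlation). Removing the trend on gene length and GC content ended that list's call (adjusted p = 0.170), as did leaving out control replicate 2 (0.0512) or on-drug replicate 2 (0.106). Smooth muscle myosin Myh11 rose by 0.32 ± 0.07, and Acta2 had 0.22 ± 0.08 with an adjusted p of 0.0909, which passed without control replicate 4 (0.0479) or on-drug replicate 1 (0.0486).

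The list with the smallest adjusted p on drug was that of the heat-shock chaperones, which fell. Of 16 genes 12 were called down and 0 up, and 15 down adjusted over the list alone (camera adjusted p = 2.4e-13, adjusted p = 0.263 with an estimated correlation). Mitochondrial Hspd1 fell by 0.57 (SE 0.09). Hspa1a and Hspa1b fell by 2.32 and 2.35 on the log2 scale, although reads shared between these near-identical copies were counted for each. Without control replicate 3, in which Hspa1a, Hspa1b and Hsp90aa1 were highest, Hspa1b fell by 1.90, and the list kept its call (camera adjusted p = 1.5e-14). The cytosolic ribosome list was lower (7 of 30 called down, 18 adjusted over the list alone, median -0.16), as was oxidative phosphorylation (4 of 30 called down, 6 adjusted over the list alone, median -0.16). Some of these calls depended on single libraries. Rps6, Rpl7 and Rps3 lost theirs in 9, 5 and 5 of the 12 fits that left out 1 library, and Cox7b, Ndufb5 and Ndufb3 in 5, 3 and 2. Other settings ended them too. Of all 27 other settings, 16, 12 and 11 ended the calls of Rps6, Rpl7 and Rps3. For Cox7b, Ndufb5 and Ndufb3 these numbers were 10, 4 and 5. The camera adjusted p of these lists were 9.0e-07 and 7.2e-07, and both had an adjusted p = 0.594 with an estimated correlation. All 25 interferon response genes had a negative log2 fold change, but 1 was called, or 2 adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.594 with an estimated correlation). That gene, Bst2, lost its call in 15 of 27 other settings, including those without control replicates 1 (0.0937), 2 (0.112) or 3 (0.0937) or on-drug replicates 1 (0.0732), 2 (0.0903), 3 (0.126) or 4 (0.0686). Clock genes differed in both directions, 9 up and 3 down of 18, or 11 up and 4 down adjusted over the list alone (camera adjusted p = 0.0082, adjusted p = 0.559 with an estimated correlation).

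Across the 8 matrix lists together, 75 of 203 genes were up on drug and 4 down, with a median log2 fold change of 0.19. The count of genes down depended on the scaling: without composition factors 1033 genes were up and 388 down, so that 72.7% of the calls were up in place of 58.4%. DESeq2 called 1474 up and 1371 down, the fit of the 2 groups alone 408 down, and the fit with the skeletal muscle genes as a covariate 624 up and 395 down. The counts also depended on single libraries, with 588 up and 346 down without control replicate 3, 513 and 312 without on-drug replicate 3, 592 and 326 without on-drug replicate 4, and 461 down without on-drug replicate 2.

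The second comparison asked how the aorta stood 1 week after withdrawal, relative to untreated mice. Lox and Fbn1 were below controls. Lox fell to 102 ± 10.1 CPM, a log2 fold change of -1.41 ± 0.08 (adjusted p = 1.3e-08), and Fbn1 to 636 ± 50.7 CPM, a change of -0.60 ± 0.07. Genes of protein folding in the endoplasmic reticulum, immediate-early genes and markers of blood were lower as well, and clock genes had shifted strongly. In total 1545 genes were higher and 1422 lower than in controls, and 131 rose and 216 fell at least 2-fold.

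Matrix genes had gone in both directions, 28 up and 39 down of 203, with a median of -0.03. The elastic fibre list had 2 up and 6 down of 23 (2 and 6 adjusted over the list alone), and the interstitial collagens 1 up and 3 down of 18 (1 and 4 adjusted over the list alone). Neither passed camera, with adjusted p of 0.169 and 0.182. Col3a1 fell from 4419 ± 465 to 2841 ± 352 CPM (-0.64 ± 0.10, adjusted p = 0.000814) and Col5a3 by 1.44 (SE 0.18). Col1a1, at 834 ± 63.8 CPM, was within the spread of the controls (adjusted p = 0.414). Some matrix genes were higher than in controls, among them the cartilage proteoglycan aggrecan (Acan, 0.90 ± 0.12), matrix Gla protein (Mgp, 0.52 ± 0.06), which inhibits calcification, and thrombospondin-2 (Thbs2, 0.58 ± 0.08).

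Chaperones of the secretory pathway fell. In the endoplasmic reticulum stress list 17 of 25 genes were called down and 0 up, with calreticulin (Calr) at 425 ± 21.9 CPM against 686 ± 24.4 CPM in controls and the disulfide isomerase Pdia6 down by 0.77 (SE 0.08). Adjusted over the list alone, 17 were down and 1 up. Camera gave an adjusted p of 2.5e-09, and an adjusted p = 0.424 followed with an estimated correlation. The general secretory list had 12 of 31 genes down and 0 up, or 15 adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.424 with an estimated correlation). The collagen chaperone Serpinh1 and the prolyl hydroxylase subunit P4ha2 fell by 0.70 (SE 0.08) and 0.66 (SE 0.10). The collagen-processing list as a whole had 5 down and 2 up of 24, or 8 down and 3 up adjusted over the list alone, and did not pass (camera adjusted p = 0.0802). Heat-shock genes were down in 7 of 16 cases, or 14 adjusted over the list alone, among them Hspa8 and Hsp90aa1 (camera adjusted p = 1.6e-07, adjusted p = 0.488 with an estimated correlation).

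Clock genes were among the genes with the largest changes in this comparison. Arntl, which encodes the core activator BMAL1, was at 17.2 ± 3.31 CPM in controls and 1.09 ± 0.263 CPM off drug (log2 fold change -3.99 ± 0.30, adjusted p = 1.1e-05). The on-drug mean lay between them, at 9.25 ± 3.22 CPM. The clock outputs Dbp and Hlf rose by 2.01 ± 0.25 and 2.22 ± 0.16 over controls, and Per3 and Cry1, repressors of the clock, by 2.08 ± 0.15 and 2.15 ± 0.14. Of 18 clock genes 10 were up and 5 down, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.0032, adjusted p = 0.424 with an estimated correlation). Immediate-early genes were down in 13 of 24 cases and up in 0, or 15 down and 2 up adjusted over the list alone, with Egr1 at 16.5 ± 2.46 CPM against 109.7 ± 13 CPM in controls. Camera gave this list 1.4e-08, with an adjusted p = 0.424 with an estimated correlation. The hour at which tissue was taken is not in the labels.

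**Figure D2:**
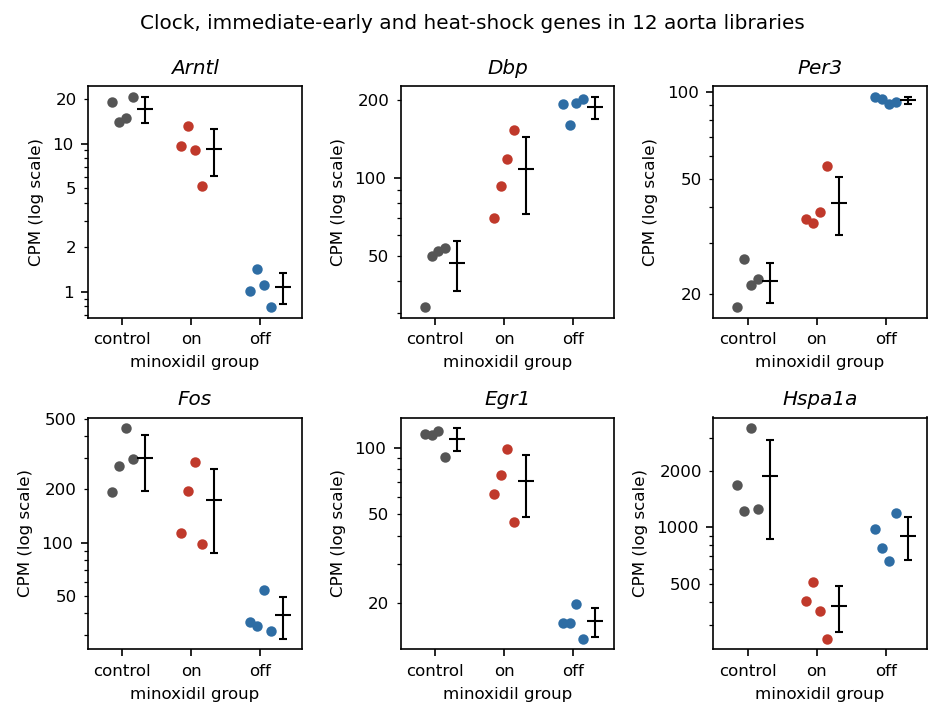
CPM (counts scaled to library size, log axis) of 3 clock genes (Arntl, Dbp, Per3), 2 immediate-early genes (Fos, Egr1) and the heat-shock gene Hspa1a in each of the 12 libraries (dots), with the mean and SD of each group of 4. Arntl fell and Per3 rose from controls to on-drug to off-drug libraries with no overlap between groups, and Hspa1a was lowest on drug.

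Erythroid, macrophage, interferon and chemokine lists were lower off drug, whereas T and B lymphocyte genes had positive medians of 0.88 and 0.73 and did not pass (camera adjusted p = 0.0802 for both). The erythroid list had 8 of 9 genes down, or 8 adjusted over the list alone, and a median of -1.81 (camera adjusted p = 2.4e-06, adjusted p = 0.493 with an estimated correlation). Haemoglobin Hbb-bs, whose reads overlap those of its paralog, averaged 3152 ± 2132 CPM in controls and 897 ± 356 CPM off drug. That call ended without control replicate 3 (0.0576) and without off-drug replicates 2 (0.0818), 3 (0.0855) and 4 (0.0840). Macrophage genes were down in 7 of 21 cases, or 10 adjusted over the list alone, including the complement subunits C1qa (-0.38 ± 0.07) and C1qb (-0.42 ± 0.07). Camera gave an adjusted p of 0.00037 (adjusted p = 0.520 with an estimated correlation). Interferon response genes were down in 9 of 25 cases, or 12 adjusted over the list alone, with Rsad2 down by 2.45 (SE 0.37); their camera adjusted p was 7.0e-06 (adjusted p = 0.520 with an estimated correlation). Inflammatory chemokines and cytokines were down in 9 of 27 cases and up in 2, or 9 and 3 adjusted over the list alone, with Ccl7 down by 2.90 (SE 0.43; camera adjusted p = 0.0070, adjusted p = 0.424 with an estimated correlation). Skeletal muscle genes had a median of 0.66, with 2 of 19 called up and 1 down, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0054, adjusted p = 0.529 with an estimated correlation). The call of Actn3 ended without control replicate 3 (0.0927) or off-drug replicates 1 (0.0572) or 2 (0.136).

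Contractile smooth muscle genes were higher off drug than in controls, with 8 of 26 up and 0 down, or 8 up and 1 down adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.624 with an estimated correlation). They included smoothelin (Smtn, 0.55 ± 0.09), and the list's call ended without off-drug replicate 1 (0.0648). The pore-forming subunit of the vascular ATP-sensitive channel, Kcnj8 (ENSMUSG00000030247.9, chromosome 6, 142564837 to 142571614), had 54.9 ± 6.08 CPM in controls, 44.7 ± 2.80 CPM on drug and 68.8 ± 7.33 CPM off drug. It was higher off drug than in controls by 0.32 ± 0.08 (adjusted p = 0.0149). On drug it was lower than in controls by a log2 fold change of -0.30 ± 0.08 (adjusted p = 0.0369), a call that 10 of 27 other settings ended, including those without control replicates 1 (0.0885), 2 (0.0729) and 3 (0.0594) and on-drug replicates 1 (0.0732), 2 (0.0892) and 4 (0.0871). The off-drug call ended without control replicate 3 (adjusted p = 0.0507), control replicate 4 (0.0528) and off-drug replicate 3 (0.0656). Its partner, the sulfonylurea receptor gene Abcc9 (ENSMUSG00000030249.15, chromosome 6, 142587862 to 142702315), was at 473 ± 35.1 CPM in controls and 558 ± 21.1 CPM off drug (0.24 ± 0.06, adjusted p = 0.0171), and 4 of 27 settings ended that call, 2 of them without control replicate 4 (0.0603) or off-drug replicate 2 (0.0509).

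Without composition factors 1867 genes were up and 844 down in this comparison, 68.9% up in place of 52.1%. With control replicate 4, which had the most haemoglobin reads, and off-drug replicate 2, which had the most skeletal muscle reads, left out together, 861 genes were up and 927 down, and with the skeletal muscle genes as a covariate 691 and 645.

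The third comparison set the off-drug libraries directly against the on-drug libraries. Matrix genes were lower off drug than on drug. Of the 203 matrix genes 93 fell and 10 rose, with a median of -0.22. Col1a1 fell by 1.01 (SE 0.11), Col3a1 by 0.88 (SE 0.10), Fbn1 by 1.00 (SE 0.07) and Lox by 1.49 (SE 0.08), each beyond the replicate spread. In total 1341 genes were higher off drug than on drug and 1706 lower, of which 172 rose and 288 fell at least 2-fold.

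Every collagen-processing gene tested had a negative log2 fold change, and 13 of 24 were called down, or 19 adjusted over the list alone. Camera gave an adjusted p of 4.2e-09 (adjusted p = 0.274 with an estimated correlation). Interstitial collagens were down in 13 of 18 cases and up in 1, or 13 and 1 adjusted over the list alone. Elastic fibre genes were down in 13 of 23 cases and up in 0, or 13 down adjusted over the list alone, and basement membrane genes in 10 of 19 cases, or 11 adjusted over the list alone. These 3 lists had camera adjusted p of 8.6e-09, 1.9e-07 and 1.6e-06, and each had an adjusted p = 0.274 with an estimated correlation. The exception among the collagens was Col27a1, chosen here as the single collagen called up. Matricellular genes were down in 14 of 34 cases and up in 3, or 18 and 3 adjusted over the list alone (camera adjusted p = 1.7e-05, adjusted p = 0.274 with an estimated correlation). Integrin and focal adhesion genes were down in 12 of 26 cases and up in 1, or 16 and 1 adjusted over the list alone (camera adjusted p = 2.0e-06, adjusted p = 0.274 with an estimated correlation). Matrix proteases and inhibitors were down in 12 of 36 cases and up in 2, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.278 with an estimated correlation), with the proteoglycan-cleaving Adamts12 down by 1.38 (SE 0.16). Fibroblast genes moved in the same direction, down in 8 of 18 cases and up in 1, or 11 and 1 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0011, adjusted p = 0.437 with an estimated correlation).

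Cell-cycle genes were lower after withdrawal than on drug. Of 30 genes 15 fell and 1 rose, or 17 and 1 adjusted over the list alone, with a median of -0.71 (camera adjusted p = 2.5e-06, adjusted p = 0.278 with an estimated correlation). The mitotic cyclin Ccnb1 was at 2.91 ± 0.420 CPM on drug and 1.06 ± 0.383 CPM off drug, and topoisomerase Top2a at 13.3 ± 2.62 and 5.41 ± 1.76 CPM. Lymphatic markers were down in 4 of 7 cases, or 7 adjusted over the list alone (camera adjusted p = 2.9e-06, adjusted p = 0.274 with an estimated correlation), with Lyve1 down by 1.24 (SE 0.14). Endothelial genes were down in 10 of 22 cases and up in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 4.9e-06, adjusted p = 0.423 with an estimated correlation). Macrophage genes were down in 11 of 21 cases, or 13 down and 1 up adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.274 with an estimated correlation), with the integrin subunit Itgam down by 1.02 (SE 0.12). Cholesterol synthesis genes rose in 6 of 22 cases and fell in 1, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00058, adjusted p = 0.440 with an estimated correlation), and Msmo1, a sterol-modifying enzyme of this pathway, rose by 0.62 ± 0.13.

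**Figure D3:**
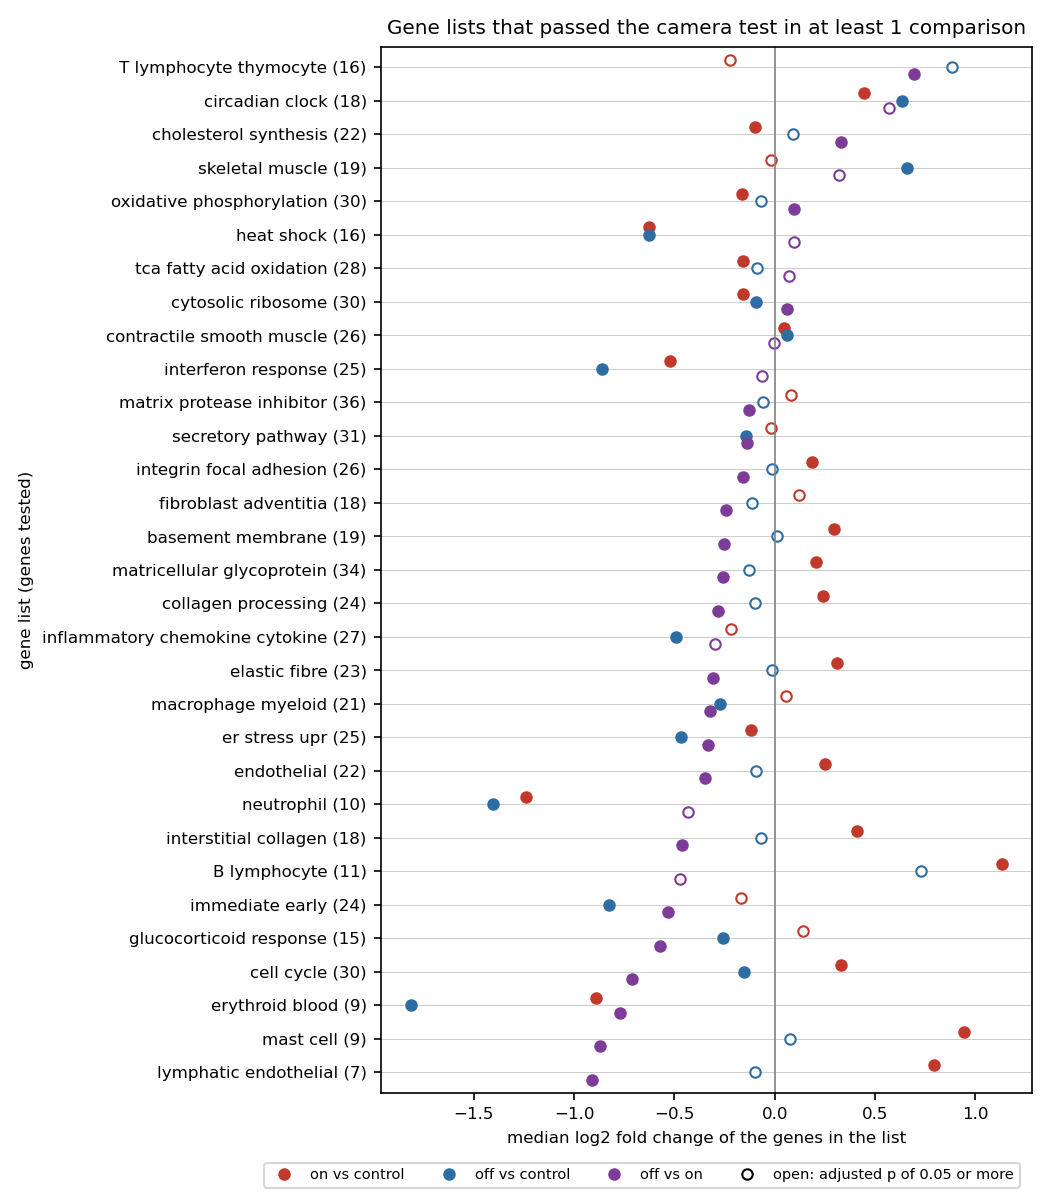
Median log2 fold change of the tested genes in each of the 31 gene lists that passed camera in at least 1 of the 3 comparisons, with the number of genes tested in brackets. Filled points passed at an adjusted p below 0.05 and open points did not; the collagen, elastic fibre and basement membrane lists lay above 0 on drug against control and below 0 off drug against on drug.

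The last question was how much of the on-drug pattern remained after withdrawal. Of the 1743 genes called on drug against control, 532 (30.5%) were also called off drug against control in the same direction, and 678 (38.9%) were called off drug against on drug in the opposite direction. Both held for 12 genes and neither for 545. These counts depended on single libraries: 921 were kept without control replicate 1, 264 without control replicate 3, 287 without on-drug replicate 3 and 290 without on-drug replicate 4. Returned genes numbered 440, 337 and 416 without on-drug replicates 2, 3 and 4, and genes with neither 348, 210 and 220 without these and 216 without control replicate 3. Among the 1018 genes up on drug, 306 stayed above controls and 451 fell again, while among the 725 genes down on drug 226 stayed below and 227 rose again. In 10 simulations with complete return of every effect, 818 of 1068 on-drug calls returned and 0.4 were kept, and in 10 simulations with complete persistence 814 of 1050 were kept and 0.2 returned. In both, the off-drug group carried no changes of its own and each gene was drawn independently. The real off-drug libraries had 2967 calls against control and 3047 against on drug. The 0.4 kept therefore gives no chance value for the 532, and the 0.2 returned gives none for the 678. The on-drug libraries also both selected these genes and entered the off against on comparison, which can inflate the number returned.

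Both comparisons against control shared their control libraries, which makes their values move together by chance. Called up in both were 306 genes, called down in both 226 and called in opposite directions 83, of which 68 were up on drug and down off drug. Single libraries moved these counts: up in both, down in both and opposite numbered 161, 103 and 44 without control replicate 3, 173, 114 and 48 without on-drug replicate 3, and 183, 107 and 51 without on-drug replicate 4. Without control replicate 1, 571 were up in both and 350 down in both. Opposite calls numbered 42 without control replicate 2, 54 without on-drug replicate 2, and 51 and 47 without off-drug replicates 3 and 4. Simulated unchanged groups set against shared controls, which were simulated as well, gave 0, 0 and 0. They held a mean of 0.3 genes called on drug against control, so calls to share were almost absent. The values of 0 therefore do not measure the overlap that shared controls cause. The simulations with complete return gave 0.3, 0.1 and 0, and those with complete persistence 524.9, 289 and 0. Their off-drug groups carried no changes of their own, unlike the real off-drug libraries. Independent lists of the observed lengths would share 63.8, 41.8 and 104, values that leave out the shared controls. Across genes, which are not independent replicates, the log2 fold changes of both comparisons had a correlation of 0.43. This lay below the 0.51 of simulated unchanged groups that shared simulated controls. The covariance was 0.0759 against 0.0513 in those simulations, a difference of 0.0246. With the controls split 2 and 2, so that no control library was shared, the median correlation over 6 splits was 0.08 and the median covariance 0.0187. The split left 73 genes up in both, 48 down in both and 47.5 in opposite directions (medians). The split also lowered the number of controls per comparison, and the genes called on drug went from 1743 to a median of 755.5, with a range of 298 to 2276. With on drug set against control replicates 3 and 4, 2276 genes were called and 248 kept, against 532 of 1743 kept with all controls. The off-drug comparison still had fewer controls there, so the split does not separate the sharing of the controls from their number.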

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

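Of the tests below, the one of tissue composition behind the clock shift was set after the fall of Arntl was known but before its values with covariates were seen. The other tests of explanations, and the counts of other splits, were chosen after the results they concern were seen.

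Chance allotment of libraries to groups was argued against as the source of the call counts, but was not excluded. Of the 35 ways to split the 8 libraries of a comparison 4 and 4, 1, the real one, gave as many calls, and no stronger result was possible with 35 splits. Each other split mixed the groups, which adds any group difference to the spread and lowers its count. Cage, day or hour of collection, which the labels do not give, could separate the groups in the same way. For on drug against control the real split called 1743 genes and the highest other split 329, which grouped control replicate 1 with on-drug replicates 2, 3 and 4. For off drug against control these counts were 2967 and 56, and for off against on drug 3047 and 1.

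Matrix genes were higher on drug, with a median log2 fold change of 0.19 over 203 genes and of 0.41 over 18 interstitial collagens. A trend with transcript length and GC content was argued against as the whole cause. After its removal the median was 0.16, between 0.11 and 0.20 in each on-drug library. Before its removal the median of 0.19 lay above 100% of 10000 random lists matched on length, GC and expression. These random lists had a median of 0.059 and do not carry any correlation among the matrix genes. The median after removal was not set against random lists. A clock effect that raises matrix genes steadily along the clock score was argued against by the off-drug libraries. These lay furthest along the score and had a matrix median of -0.029. A clock effect that is largest at the on-drug position cannot be told apart in this way. The off-drug libraries also differed by withdrawal and age. More adventitial fibroblasts could account for part of the on-drug rise. The 13 fibroblast markers outside the matrix lists had a median of 0.16 with quartiles of -0.01 and 0.28. For the pooled matrix genes this cannot be told apart from a change within cells. For the interstitial collagens the upper quartile of 0.28 lay below their median. The on-drug libraries lay at 0.14 to 0.21 for the markers and 0.29 to 0.56 for the collagens. Of the markers 3 were called up and 1 down. Cd248 and Ebf2, chosen after their values were seen, rose by 0.57 and 0.54, above the collagen median of 0.41. A larger share of fibroblasts is therefore not excluded for the collagens either. The effect of the drug on matrix expression stays open as the biological explanation, and it was not tested apart from these; for the fall from on to off drug the share of fibroblasts stays open too, as the fibroblast list had a median of -0.24 beside -0.22 for the matrix genes.

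The clock score, a mean over 10 clock genes, shifted between the groups in a graded way, from -0.94 in controls to -0.13 on drug and 1.07 off drug. These genes and their signs were chosen after the data were seen, which favours grading and a large share of variance between groups. Cry1, a clock gene outside the score, was not graded. It ran from 4.68 to 5.62 CPM in controls, 3.50 to 5.69 CPM on drug and 21.4 to 23.8 CPM off drug. A change in tissue composition was argued against, because with scores of fat, skeletal muscle or immune genes in the fit the off-drug log2 fold change of Arntl was between -4.52 and -4.02, the latter with an SE of 0.32. The time of day of collection is a candidate explanation that cannot be told apart from an effect of the drug or its withdrawal, since 94.3% of the variance of the score lay between the 3 groups and the labels give no hour. The extra week of age off drug stays open and was not tested.

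Elastin stood below controls after the drug-free week, at a log2 fold change of -1.03. Reads shared with the overlapping gene Gm43278 were argued against, as its count reached at most 4.35% of that of Eln in any library. A lower share of smooth muscle was argued against by the contractile list, whose median was 0.064 and whose off-drug libraries lay between 0.04 and 0.18 where Eln lay between -1.17 and -0.82. Collection conditions that go with the clock shift may contribute and cannot be told apart, because with the clock score in the fit the change was 0.37 with an SE of 0.77, against an SE of 0.21 without it. Withdrawal of the drug and age stay open as biological explanations and were not tested.

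For 12 named genes the on-drug and off-drug groups differed from controls in opposite directions, and the difference between the groups was itself called. From on to off drug Fbn1 fell by 1.00 on the log2 scale, and the log2 fold changes were -1.05 for Loxl2, -1.24 for Lyve1, -0.67 for Nid1, -0.65 for Col4a1, -0.72 for Mfap5, -0.60 for Adamts2, -2.42 for Esm1, -1.02 for Itgam, -0.66 for Ly6a and -0.82 for Tnc, all higher than controls on drug and lower off drug. Kcnj8 went the other way, with 0.62.

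Single libraries lay far from the other 3 of their group in 33 of 480 groups tested over 160 named genes, where chance alone gives about 1 in 20, or 24. Of these 33, 30 are given here. All values that follow are in CPM, each followed by the range of the other 3 libraries. Control replicate 1 was high for Cited2 at 17.8 (10.7 to 11.8), and control replicate 2 for Adamts5 at 58.1 (48.4 to 49.7). Control replicate 4 was high for Cry2 at 20.1 (14.5 to 14.9) and Ndufb5 at 62.0 (50.4 to 52.2). On-drug replicate 1 was low for Cry2 at 19.6 (28.1 to 28.9), Mgp at 1566 (1729 to 1741) and Smtn at 150.1 (181 to 186), and high for Msmo1 at 26.6 (17.5 to 18.2). On-drug replicate 2 was high for Lox at 337 (265 to 275), Synpo2 at 546 (515 to 517) and Ccl2 at 4.33 (2.12 to 2.22). On-drug replicate 3 was low for Abcc9 at 456 (496 to 502), and high for Ckm at 4.93 (3.62 to 3.78), Kdelr3 at 71.9 (68.2 to 68.6), Rag1 at 0.584 (0.0734 to 0.158) and Rbm12b2 at 14.7 (6.32 to 7.07). On-drug replicate 4 was low for Nfil3 at 3.88 (6.45 to 6.66) and high for Per3 at 55.4 (35.2 to 38.5). Off-drug replicate 1 was high for Prox1 at 0.852 (0.587 to 0.627), Itga9 at 538 (487 to 494) and Mvk at 18.2 (14.1 to 14.4), and off-drug replicate 2 for Itgam at 8.78 (6.63 to 6.93). Off-drug replicate 3 was low for Dnajb1 at 57.0 (71.7 to 74.3) and P4ha2 at 31.9 (36.3 to 36.5), and high for Mgp at 2895 (2594 to 2623), Ccnb2 at 1.14 (0.490 to 0.599) and Dntt at 5.54 (0.537 to 1.3). Off-drug replicate 4 was high for Msmo1 at 35.3 (29.1 to 30.0) and Lama2 at 253 (246.5 to 247), and low for Cd34 at 219 (238 to 239.7).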

How the results depend on the processing

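The clock score covariate, the removal of the length and GC trend and the exclusion of 2 libraries together were chosen after seeing the data; the other settings were planned. Of 226 results for named genes, 180 had the same call in each setting that tested them, other than the fold minimum and the clock covariate (27 settings, or 26 for the 3 results whose genes the stricter filter removed), 43 lost it in at least 1, 3 gained one and 0 reversed. The clock covariate ended 204 with the sign kept and a further 9 with the sign changed, and the fold minimum ended 141, the latter by construction. Of the others, the skeletal muscle covariate (30) and leaving out on-drug replicate 3 (25) ended most. Median log2 fold changes of all genes stayed within 0.05 of 0 under each scaling. Counts not mentioned below stayed within 1.5 times the reported ones.

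On drug against control, the genes down numbered 388 with library size only, 408 with the 2 groups alone (fewer samples) and 1371 with DESeq2. With the skeletal muscle covariate 624 were up and 395 down on drug, and 691 and 645 off drug against control. With library size only 844 were down off drug against control. Without the 2 libraries 861 were up and 927 down there, and 7 lists were up. A minimum of 2-fold left 64 up and 75 down on drug, 131 and 216 off drug against control, and 172 and 288 off against on drug. The fold minimum acts by construction, and for the other settings the cause was not tested.

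With the clock covariate 5 genes were up and 2 down on drug, 0 and 0 off drug against control and 9 and 28 off against on drug in edgeR, with 2049, 1326 and 2249 genes at an unadjusted p below 0.05. The median SE off drug against control rose from 0.15 to 0.62, as the score nearly coincides with the groups. It gave 6 lists up off drug against control. In that comparison 9 named genes changed sign without a call: Adamts4 (1.01), Cdkn1a (0.19), Ciart (-0.24), Dbp (-0.76), Eln (0.37), Itgb3 (0.54), Mybpc2 (0.53), Oas1a (0.80) and Sec61g (0.17).

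With an estimated correlation 0 lists passed up and 0 down in each comparison, the lowest adjusted p being 0.263, 0.424 and 0.274, and 7, 3 and 5 lists had an unadjusted p below 0.05. Fry passed 1 list down on drug and 2 up off against on drug; the cause was not tested.

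Genes up in both, down in both and opposite numbered 478, 440 and 157 with DESeq2, 576, 453 and 155 at an adjusted p of 0.10, and 73, 48 and 47.5 (medians) with the controls split. On-drug calls kept, returned and neither numbered 918, 1081 and 877, then 1029, 1178 and 819, then 121, 404 and 230. The looser threshold acts by construction, and the split changed the number and the sharing of the controls at once; the cause with DESeq2 was not tested.

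Leaving out 1 library at a time, genes up on drug ranged from 513 to 1406 and down from 312 to 913, off drug against control from 1034 to 1992 and from 974 to 1614, and off against on drug from 940 to 1447 and from 1305 to 1834. Up in both ranged from 161 to 571, down in both from 103 to 350 and opposite from 42 to 106. Kept ranged from 264 to 921, returned from 337 to 932 and neither from 210 to 731. Lists up and down ranged from 11 to 14 and 5 to 10 on drug, 3 to 7 and 11 to 16 off drug against control, and 2 to 5 and 18 to 20 off against on drug. Changes beyond 1.5 times came without control replicate 1 (571, 350 and 921 kept; 7 lists up off drug), 2 (opposite 42), 3 (588 up and 346 down on drug; 161, 103 and 44; kept 264, neither 216; 5 lists up off drug) and 4 (5 lists down on drug, 5 up off drug). They also came without off-drug replicate 1 (5 lists up off drug), 3 (opposite 51; 2 lists up off against on drug) and 4 (opposite 47), and on-drug replicate 2 (461 down; opposite 54; returned 440, neither 348), 3 (513 and 312; 173, 114 and 48; 287, 337 and 210) and 4 (592 and 326; 183, 107 and 51; 290, 416 and 220).

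The replicate block moved no count beyond 1.5 times, and the numbers did not pair the samples: correlations of same-number libraries ran from -0.080 to 0.067, and 3 of 12 libraries were closest to their own number. The Xist covariate and the series-table counts were not run. Depth was not varied. At the real library sizes and 4 mice per group, 28% to 36% of 1.3-fold changes were recovered in simulated data.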

Other observations

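No test below bears on a cause. The lists of this part were tested as planned; genes outside the naming rule are marked.

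Further lists passed camera on drug against control, all with an adjusted p of at least 0.594 with an estimated correlation. All 11 B lymphocyte genes had a positive log2 fold change, with a median of 1.14 and 0 called over all genes, or 3 adjusted over the list alone (camera adjusted p = 0.0017). Neutrophil genes had a median of -1.24 and erythroid genes of -0.89, with 0 of 10 and 0 of 9 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0113 and 0.0117). The erythroid call ended without control replicate 4 and off-drug replicate 2 (adjusted p = 0.249). Cell-cycle genes had a median of 0.33, with 3 of 30 up, or 11 up and 1 down adjusted over the list alone (camera adjusted p = 0.00081). Of the 3, Cenpa lost its call without control replicates 1 (0.0525), 2 (0.0830) or 4 (0.0561) or on-drug replicates 2 (0.0794) or 3 (0.0734), Cenpe without control replicate 3 (0.0537) or on-drug replicates 3 (0.0726) or 4 (0.0504) and Tpx2 without on-drug replicate 3 (0.0708). Cholesterol synthesis genes were down in 3 of 22 cases, or 4 adjusted over the list alone (camera adjusted p = 0.0268), among them Cyp51 (-0.83 ± 0.17) and Msmo1 (-0.51 ± 0.13). The endoplasmic reticulum stress list had a median of -0.12 with 1 of 25 down, or 4 adjusted over the list alone (camera adjusted p = 0.0147). Genes of the citric acid cycle and fatty acid oxidation had a median of -0.16 with 0 of 28 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0411). Leaving out 1 library ended some of these calls. The B lymphocyte call ended without on-drug replicate 2 (0.0520), the neutrophil call without control replicate 4 (0.114) or on-drug replicate 2 (0.0808) and the erythroid call without control replicate 4 (0.224) or on-drug replicate 2 (0.0739). The cholesterol call ended without control replicate 1 (0.187), control replicate 2 (0.105), on-drug replicate 3 (0.0580) or on-drug replicate 4 (0.132), and that of endoplasmic reticulum stress without control replicate 3 (0.112), control replicate 4 (0.0609), on-drug replicate 1 (0.0510) or on-drug replicate 4 (0.0777). The call of the citric acid cycle list ended without control replicate 1 (0.383), control replicate 4 (0.463), on-drug replicate 1 (0.130) or on-drug replicate 2 (0.127). The call of Cyp51 ended without on-drug replicate 3 (0.0504), and that of Msmo1 without control replicates 1 (0.0582), 2 (0.0666) or 4 (0.0503) or on-drug replicates 2 (0.0713), 3 (0.0841) or 4 (0.0870).

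Off drug against control, neutrophil genes had a median of -1.40 with 0 of 10 called, or 6 down adjusted over the list alone (camera adjusted p = 0.00084, 0.577 with an estimated correlation). Glucocorticoid response genes had a median of -0.26 with 1 of 15 called in both counts, Cdkn1a at -1.18 ± 0.17 (camera adjusted p = 0.0157, 0.640 with an estimated correlation). Cell-cycle genes were down in 7 of 30 cases and up in 1, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0497, 0.771 with an estimated correlation), a call that ended with DESeq2 size factors (adjusted p = 0.0526). The ribosome list had a median of -0.09 with 1 of 30 down, or 0 adjusted over the list alone (camera adjusted p = 0.0200, 0.771 with an estimated correlation). The cell-cycle call also ended without control replicate 2 (0.10), control replicate 3 (0.127), off-drug replicate 4 (0.177), on-drug replicate 1 (0.0658), on-drug replicate 2 (0.0518) or on-drug replicate 4 (0.0615). The glucocorticoid call ended without control replicate 1 (0.0683) and the ribosome call without control replicate 3 (0.182), off-drug replicate 2 (0.0717) or off-drug replicate 4 (0.134).

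Off drug against on drug, the endoplasmic reticulum stress list was down in 15 of 25 cases and up in 2, or 16 and 2 adjusted over the list alone (camera adjusted p = 1.4e-06). The secretory list was down in 7 of 31 cases, or 13 adjusted over the list alone (camera adjusted p = 5.5e-07), and immediate-early genes in 13 of 24 cases and up in 1, or 14 and 2 adjusted over the list alone (camera adjusted p = 1.3e-06). Glucocorticoid response genes were down in 6 of 15 cases in both counts, with Fkbp5 at -1.03 ± 0.24 (camera adjusted p = 0.0023). Mast cell genes were down in 2 of 9 cases, or 4 adjusted over the list alone (camera adjusted p = 0.0028), and erythroid genes in 1 of 9 cases, or 3 adjusted over the list alone (camera adjusted p = 0.0021). Oxidative phosphorylation and ribosome genes had medians of 0.10 and 0.06 with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0121 and 0.0394). The adjusted p of these 8 lists with an estimated correlation lay between 0.274 and 0.818. The oxidative phosphorylation call ended without off-drug replicate 3 (0.201) or off-drug replicate 4 (0.0564) and the ribosome call without off-drug replicate 1 (0.186), off-drug replicate 3 (0.152), on-drug replicate 3 (0.138) or on-drug replicate 4 (0.0930). The mast cell calls ended for Cpa3 without off-drug replicates 1 (0.0840) or 2 (0.0834) or on-drug replicates 1 (0.0644), 3 (0.0927) or 4 (0.0681), and for Mrgprb1 without off-drug replicates 1 (0.108), 2 (0.111) or 3 (0.0660) or on-drug replicates 1 (0.0726), 2 (0.0869) or 3 (0.0907). The call of Fkbp5 ended without off-drug replicates 2 (0.0550), 3 (0.0598) or 4 (0.0523).

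T lymphocyte and thymocyte genes were higher off drug than on drug, with 2 of 16 up in both counts (camera adjusted p = 0.0208, 0.736 with an estimated correlation). Both were thymocyte genes near the detection limit on drug. Rag1 was at 0.233 ± 0.236 CPM on drug and 5.96 ± 6.60 CPM off drug, and Dntt at 0.0869 ± 0.0427 and 2.03 ± 2.37 CPM. In single off-drug libraries Rag1 ran from 0.979 to 15.6 CPM, and in controls from 0.182 to 6.20 CPM. The list passed neither without off-drug replicate 3 (0.115) nor without on-drug replicate 4 (0.156). The call of Rag1 ended in 9 of the 12 fits that left out 1 library, without control replicates 2 (0.0560) and 3 (0.0580), off-drug replicates 2 (0.0565), 3 (0.101) and 4 (0.0727), and each on-drug replicate (0.108, 0.113, 0.0688 and 0.111 for 1 to 4). That of Dntt ended without each on-drug replicate (0.0725, 0.0718, 0.0588 and 0.0698).

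Lists that passed in no comparison numbered 15 of 46. They were proteoglycans, potassium channels, calcium handling, vasoactive and renin-angiotensin genes, TGF-beta and BMP signalling, pericytes, white and brown adipocytes, cardiac muscle, Schwann cells, sympathetic neurons, mesothelium, cartilage and bone, glycolysis and hypoxia, and sex-linked genes. Median and mean differed in sign for 6, 3 and 2 of the 46 lists in the 3 comparisons, and 0 of these had passed. The potassium channel list had 4 of 14 up and 0 down off drug against control in both counts (camera adjusted p = 0.0802, fry 0.0094). These were Kcnj8, Abcc9, Kcnj11, which rose from 1.54 ± 0.114 to 2.36 ± 0.521 CPM with an adjusted p of 0.0319 that 10 of 27 settings ended, and Kcnma1, chosen after its values were seen (0.36, adjusted p = 0.00071). Of these settings 6 left out 1 library: control replicate 2 (0.0637), 3 (0.0563) or 4 (0.0846), or off-drug replicate 2 (0.0723), 3 (0.108) or 4 (0.0818).

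Among the largest single changes, Igfbp2, which encodes an insulin-like growth factor binding protein, rose from 6.49 ± 1.31 to 19.4 ± 4.76 CPM on drug, and the transcriptional repressor Nfil3 fell by 1.76 (SE 0.31). Mir143 and Mir145a rose by 1.47 ± 0.24 and 1.21 ± 0.24 on drug, in reads shared with the longer transcript around them. Off drug against control the mitochondrial folate enzyme Mthfd1l rose by 2.30 ± 0.13, from 5.02 ± 0.382 to 24.7 ± 1.05 CPM, and the mitochondrial carrier Slc25a34 fell by 2.51 (SE 0.23). Against on drug, Cited2 rose by 2.09 ± 0.22 and the endothelial gene Esm1 fell by 2.42 (SE 0.19), from 12.9 ± 1.91 to 2.38 ± 0.20 CPM.

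Across 16892 genes with a mean log2 CPM above 0, which are not independent replicates, log2 fold changes on drug against control had Spearman correlations of 0.15 with transcript length and 0.28 with GC content. These were 0.08 and 0.20 off drug against control, and -0.06 and -0.04 off against on drug.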
